A study of Mus musculus with 22 samples.

How the data were processed

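Liver polyA RNA of 22 male CD2F1 mice in 3 groups was analysed: CT (sham-injected, n = 6), C26 (C26 tumour cells, n = 8) and C26-TDCA (C26 tumour cells and 10 mg/kg TDCA daily, n = 8). RNA was extracted from frozen liver with Trizol and treated with DNase, and libraries were made by Illumina protocols, per the labels. The deposited table holds raw read counts per Ensembl gene, with 1 column per mouse, and the counts were used as the authors deposited them. Per the submitters' processing notes, the tools included bcl2fastq 2.17, FastQC, Trimmomatic 0.40, HISAT2 2.2.1, featureCounts 2.0.3 and DESeq2 1.42.0, and the genome build was GRCm38. The annotation release, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes that overlap or have an antisense partner, and members of families with near-identical copies, are therefore uncertain.

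The table holds 15448 genes, each with at least 10 counts in some library, so that genes with fewer counts were not analysed here. Of these, 15438 matched a symbol in GENCODE M21, an annotation of GRCm38 used here, 10 did not, and 13217 were annotated as protein coding. Columns were assigned to mice by their names, and each mouse to its group by the labels. Depth ranged from 16.5 to 28.3 M counts. At these depths, 3 counts were 0.18 CPM in the smallest and 0.11 CPM in the largest library.

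Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 14785 and removed 663. Libraries were scaled by TMM, dispersions were estimated over all 22 libraries in 1 model with a mean per group, and the 3 contrasts were tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are from this model, and each standard error is the absolute log2 fold change over the square root of F, an approximation. Approximate 95% intervals use these errors. Levels are TMM-normalised counts per 1e6 (CPM), given as mean ± SD. The median biological coefficient of variation was 15.1%. Principal components were computed on log2 CPM with a prior count of 2.

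In all, 40 gene lists with 800 entries, 29 of pathways and hepatocyte zones and 11 of markers of other cell types, were fixed before the data were examined, as were the design, the rule for named genes and the alternatives not named as chosen later. The lists overlap in some genes, and hepatocytes also express some marker and matrix genes. The pathway lists covered cholesterol synthesis, cholesterol uptake and sensing, LXR targets, lipoproteins, bile acid synthesis, bile transporters, bile acid receptors, positive and negative acute phase proteins, cytokines, interferon-stimulated genes, fatty acid oxidation, lipogenesis, gluconeogenesis and glycogen, urea cycle and amino acid catabolism, drug metabolism, growth hormone and male-biased genes, the circadian clock, glucocorticoid targets, the unfolded protein and integrated stress responses, NRF2 targets, the cell cycle, extracellular matrix, oxidative phosphorylation, ribosomal proteins, the proteasome, complement and coagulation, and pericentral and periportal hepatocytes. The marker lists covered Kupffer cells, monocytes and neutrophils, sinusoidal endothelium, stellate cells, cholangiocytes, T and NK cells, B and plasma cells, erythroid cells, exocrine pancreas, adipocytes and intestinal epithelium.

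Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 40 lists in each comparison. Camera with the correlation estimated per list, with DESeq2 size factors and with the length and GC trend removed (chosen later) were alternatives. Fry, which tests whether a list moves in 1 direction on balance and does not compare it with other genes, was another. The camera test with the trend removed used log2 CPM in place of voom values, over genes with a known transcript length. Named genes were up to 6 with the highest and 6 with the lowest log2 fold change among called genes with at least 10 CPM in the higher group and an established symbol, up to 4 called members of each list by p (up to 2 where none was called), and 15 genes of bile acid and cholesterol metabolism named in every comparison. The text names some of the genes that this rule gives; some are not reported here.

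Total counts, detected genes, the share of the 20 most abundant genes, the mitochondrial share and the slopes of log2 CPM on transcript length and GC were compared by two-sided exact permutation tests, adjusted over 21 tests; the 2 slopes were added after the data were seen. Length and GC are those of the longest transcript in GENCODE M21. A loess trend with a span of 0.3 on both was removed per library as an offset in an alternative fit, which was also chosen later, as were the fits without C26 01 and C26-TDCA 08. Other alternatives were DESeq2 size factors, upper-quartile scaling, no filter, the 2 groups of a comparison alone, the replicate number as a block, glmTreat at 0.5 log2 units, the Wald test of DESeq2 1.42.0, limma voomWithQualityWeights, and each library left out in turn.

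The edgeR step was tested on simulated data with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold per comparison. Of the 2-fold changes that passed the filter, 84.6% of 65 were recovered for C26 against CT (14112 genes tested), 84.8% of 66 for C26-TDCA against C26 (14364 genes) and 84.1% of 63 for C26-TDCA against CT (14115 genes). Unchanged genes made up 3.64%, 6.43% and 3.80% of the calls. The simulated counts were independent between genes and held no length or GC trend, so these shares need not hold for the real calls. The list test found the 1 shifted list in each simulated comparison, and called 1 of 12 unchanged lists in C26 against CT and 0 in the others.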

Results

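Liver polyA RNA was sequenced from 22 male CD2F1 mice, the hybrid of the BALB/c and DBA/2 strains in which the mouse colon carcinoma C26 is grown as a model of cancer cachexia. The control group (CT, n = 6) received a sham injection, the C26 group (n = 8) received tumour cells, and the C26-TDCA group (n = 8) received tumour cells and 10 mg/kg of taurodeoxycholic acid (TDCA) daily into the peritoneum. TDCA is the taurine conjugate of deoxycholic acid, a secondary bile acid that gut bacteria make. The libraries held 16.5 to 25.3 M counts in CT, 17.5 to 28.1 M in C26 and 20.5 to 28.3 M in C26-TDCA, so that 3 counts corresponded to 0.18 CPM (counts per 1e6) in the smallest library and 0.11 CPM in the largest. Replicates are given as separate mice in the design text. To look for a library deposited in 2 copies, the counts of each pair within a group were compared with sampling noise, and no pair was that close (chi-square per degree of freedom at least 11); this does not test whether the mice were independent.

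Principal component 1 held 60.7% of the variance and set the 6 CT libraries, at -92.7 to -85.0, apart from the 16 tumour libraries, at 4.01 to 51.5. The 20 most abundant genes took 21.8% ± 0.14 (SD, n = 6) of the counts in CT and 37.6% ± 2.27 (n = 8) in C26 (two-sided exact permutation test, p = 0.000333, the smallest that 3003 regroupings can give, adjusted p = 0.00117 over 21 tests). Mitochondrially encoded genes took 5.85% ± 0.22 in CT and 3.30% ± 0.39 in C26 (exact permutation p = 0.000333, adjusted p = 0.00117). Between C26-TDCA and C26 these shares were not called, with exact permutation p-values of 0.344 and 0.409.

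**Figure D1:**
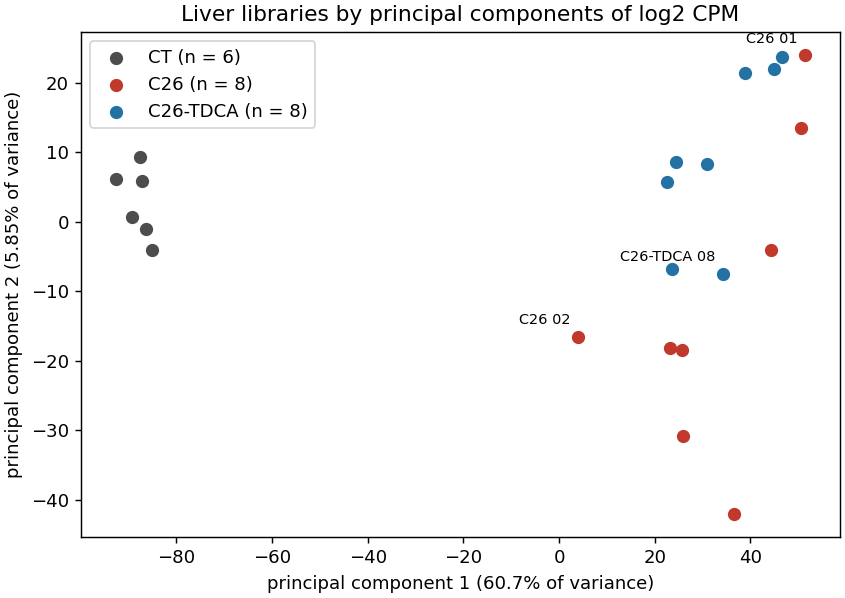
Principal components 1 and 2 of log2 CPM, with 1 point per library and colours for the 3 groups. The CT libraries lie at -92.7 to -85.0 on component 1, and the tumour libraries at 4.01 to 51.5; 3 libraries that the text names are labelled.

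The first comparison asked how the liver of tumour-bearing mice differed from that of sham-injected mice. In C26 livers the transcripts of secreted acute phase proteins rose many-fold, while those of bile acid synthesis, lipid synthesis, drug metabolism and oxidative phosphorylation fell. Of these lists, only that of the acute phase proteins was also called with an estimated correlation, and the other 4 had an adjusted p of 0.279 with it. Lcn2, which encodes the siderophore-binding lipocalin 2, went from 2.79 ± 2.79 CPM (SD, n = 6) to 2261 ± 285 CPM (n = 8), and Saa2, which encodes serum amyloid A2, from 20.2 ± 26.1 to 26140 ± 3459 CPM. Car3, the abundant carbonic anhydrase 3 of male liver, went from 4400 ± 243 to 48.9 ± 105 CPM, and Cyp3a11, a major drug-metabolising cytochrome P450, from 2737 ± 389 to 58.2 ± 106 CPM. Single libraries weighed on these means: without CT 05 the CT means were 1.67 CPM for Lcn2 and 9.62 CPM for Saa2, and without C26 02 the C26 means were 11.8 CPM for Car3 and 21.8 CPM for Cyp3a11. Of 14785 genes tested with edgeR, 4266 were higher and 4321 lower in C26 at an adjusted p under 0.05, and 1560 of the higher and 1112 of the lower genes changed more than 1 log2 unit. A test against a log2 fold change of 0.5 (glmTreat) called 1980 higher and 1633 lower genes.

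Of the 32 positive acute phase genes, 31 rose and 1 was not called, with the same counts adjusted over the list alone. Their median log2 fold change was 4.09, and the list was called by camera (adjusted p = 1.24e-31) and also held with an estimated correlation (adjusted p = 0.00327 with an estimated correlation). Itih4, a plasma inhibitor heavy chain, went from 1762 ± 123 to 28640 ± 2054 CPM (log2 fold change 4.02, SE 0.08, adjusted p = 2.46e-22), and Apcs, which encodes serum amyloid P, from 226 ± 29 to 5051 ± 336 CPM (4.48, SE 0.09, adjusted p = 2.46e-22). A2m, which encodes the protease inhibitor alpha-2-macroglobulin, was the gene with the highest log2 fold change among those named by level (11.43, SE 1.33), at 5704 ± 5249 CPM in C26 and 1.97 CPM in CT, or 0.196 CPM without CT 05. Acpp, a phosphatase, and Trat1, a T cell receptor adaptor, stood at 35.7 ± 21.2 and 40.9 ± 29.8 CPM in C26 and at 0.03 and 0.04 CPM in CT, below the level of 3 counts. Reg3b, which encodes a secreted lectin, stood at 64.9 ± 73.8 CPM in C26 and was detected in 1 CT library, at 0.226 CPM. Reads of Saa2, Orm and other near-identical family members may have been split between copies, so the single members are uncertain.

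Of the 12 negative acute phase genes, 5 rose, 4 fell and 3 were not called, the same counts as adjusted over the list alone, and the list was not called (camera adjusted p = 0.721). Alb, which encodes albumin, fell from 42190 ± 2760 to 15180 ± 2840 CPM (-1.48, SE 0.11), and Ttr, which encodes the thyroxine carrier transthyretin, fell by 1.80 (SE 0.16). Trf, which encodes transferrin, and Fetub, a fetuin, rose by 1.23 (SE 0.10) and 1.44 (SE 0.10). Of 35 complement and coagulation genes, 18 rose, 9 fell and 8 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.000361; adjusted p = 0.271 with an estimated correlation). C3, the central complement component, rose from 6327 ± 585 to 30770 ± 1338 CPM (2.28, SE 0.07).

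Of 17 measured cytokine and chemokine genes, 13 rose, 1 fell and 3 were not called (13 and 2 adjusted over the list alone), and the list was called by camera (adjusted p = 0.00769; adjusted p = 0.337 with an estimated correlation). The neutrophil chemokine Cxcl1 rose from 12.4 ± 3.8 to 324 ± 37 CPM, and Cxcl14 rose by 6.65 (SE 0.27). Cxcl9, an interferon-gamma-induced chemokine, fell by 2.94 (SE 0.27). Of 25 interferon-stimulated genes, 3 rose, 13 fell and 9 were not called, the same counts as adjusted over the list alone (camera adjusted p = 0.0266, downwards; adjusted p = 0.551 with an estimated correlation). The GTPase gene Igtp fell by 1.25 (SE 0.17), while Stat2 rose by 0.54 (SE 0.06).

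The genes of cholesterol synthesis did not move together. Of 20 enzymes, 4 rose, 4 fell and 12 were not called (2 and 4 adjusted over the list alone). Sqle, which encodes squalene epoxidase, rose from 22.9 ± 5.5 to 92.7 ± 40.7 CPM (log2 fold change 2.01, SE 0.34, adjusted p = 1.98e-05), while Tm7sf2 and Sc5d, which act late in the pathway, fell by 1.35 (SE 0.25) and 0.94 (SE 0.15). Hmgcs1, a synthase early in the pathway, rose by 1.02 (SE 0.42, adjusted p = 0.0399; not called with voomWithQualityWeights, at 0.96). The list was not called (camera adjusted p = 0.939), and its median (0.18) and mean (0.11) lay above 0 where camera's direction was down.

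Of 18 measured genes of cholesterol uptake and sterol sensing, 7 rose, 8 fell and 3 were not called, and these counts were the same adjusted over the list alone (camera adjusted p = 0.948). Npc1, a lysosomal cholesterol exporter, fell by 1.04 (SE 0.08). Lrp1, a remnant lipoprotein receptor, rose from 804 ± 92 to 2274 ± 198 CPM, the acyltransferase Soat2, which esterifies cholesterol, by 0.93 (SE 0.11) and Srebf2, the transcription factor of sterol synthesis, by 0.44 (SE 0.12; 0.26 and not called with the length and GC trend removed). The list median was 0.03 and its mean -0.05. Of 15 LXR target and efflux genes, 5 rose, 8 fell and 2 were not called (6 and 8 adjusted over the list alone; camera adjusted p = 0.515). Abca1, the cholesterol efflux transporter, rose from 196 ± 25 to 366 ± 128 CPM (0.91, SE 0.18), while Cyp46a1, a cholesterol hydroxylase, fell by 4.11 (SE 0.22). Of 23 lipoprotein genes, 2 rose, 15 fell and 6 were not called, the same adjusted over the list alone (camera adjusted p = 0.00242; adjusted p = 0.279 with an estimated correlation). Apoa2, an apolipoprotein of high density lipoprotein, fell by 1.10 (SE 0.12).

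Bile acid synthesis fell as a group. Of 17 measured genes of synthesis and conjugation, 2 rose, 12 fell and 3 were not called, the same counts as adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.279 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of the classic pathway, on chromosome 4 from 6265612 to 6275633 on the minus strand in GRCm38, fell from 374 ± 169 CPM (n = 6) to 25.1 ± 18.6 CPM (n = 8; -3.90, SE 0.62, adjusted p = 8.37e-06). Cyp8b1, which directs synthesis to cholic acid, fell from 323 ± 32 to 78.7 ± 34.2 CPM (-2.04, SE 0.28), and Cyp27a1, the entry enzyme of the alternative pathway, fell by 1.21 (SE 0.18). Cyp7b1 was not called (-0.19, SE 0.28, adjusted p = 0.567). Akr1d1, the steroid 5-beta-reductase, fell by 1.85 (SE 0.21), and Baat, which conjugates bile acids to taurine, by 0.69 (SE 0.09).

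Of 15 measured transporters of bile acids and bile, 2 rose and 13 fell, also when adjusted over the list alone (camera adjusted p = 5.73e-05; adjusted p = 0.0959 with an estimated correlation). Slc10a1, the sodium-dependent uptake transporter of the basolateral membrane, on chromosome 12 from 80953183 to 80968705 on the minus strand in GRCm38, fell from 687 ± 48 to 258 ± 49 CPM (-1.42, SE 0.10). The canalicular export pumps Abcb11 and Abcc2 fell by 0.94 (SE 0.15) and 1.43 (SE 0.12). Of 12 measured receptor genes, 4 rose, 4 fell and 4 were not called (5 and 4 adjusted over the list alone; camera adjusted p = 0.715). The bile acid receptor gene Nr1h4 fell by 0.54 (SE 0.14), and its target Nr0b2 was not called (-0.21, SE 0.25, adjusted p = 0.485). S1pr2, a receptor for conjugated bile acids, rose by 1.44 (SE 0.11). The list median was -0.02, its mean -0.18 and camera's direction up, and the median lay at 0.05 with upper-quartile scaling.

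**Figure D2:**
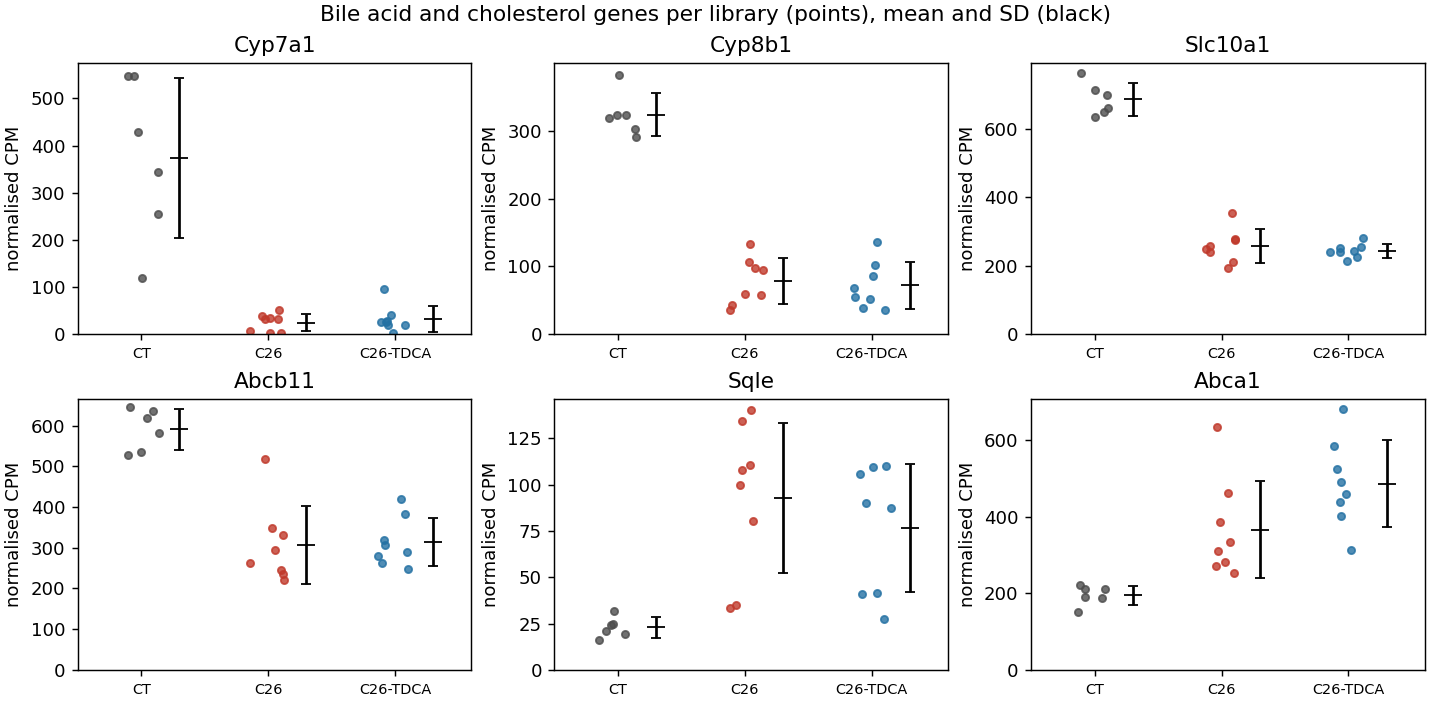
Normalised CPM of 6 genes of bile acid and cholesterol metabolism, with 1 point per library and the mean and SD in black, for CT (n = 6), C26 (n = 8) and C26-TDCA (n = 8). Cyp7a1 lay at 374 ± 169 CPM in CT, 25.1 ± 18.6 in C26 and 32.2 ± 27.9 in C26-TDCA.

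Of 21 genes of lipogenesis and triglyceride synthesis, 20 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 2.07e-07; adjusted p = 0.279 with an estimated correlation). Pklr, the liver pyruvate kinase, fell by 2.88 (SE 0.27), Me1, the cytosolic malic enzyme, by 2.29 (SE 0.21) and Dgat2, the last step of triglyceride synthesis, by 1.31 (SE 0.11), while Agpat2 rose by 0.75 (SE 0.07). Of 31 genes of fatty acid oxidation and PPAR-alpha targets, 3 rose, 20 fell and 8 were not called (3 and 21 adjusted over the list alone; camera adjusted p = 9.48e-05; adjusted p = 0.280 with an estimated correlation). Acaa1b, a peroxisomal thiolase, fell from 432 ± 44 to 17.8 ± 4.9 CPM. Of 17 genes of gluconeogenesis and glycogen, 4 rose, 10 fell and 3 were not called, the same adjusted over the list alone (camera adjusted p = 0.0340; adjusted p = 0.371 with an estimated correlation). Ugp2, which makes the glucose donor for glycogen, fell by 2.50 (SE 0.09), and Gys2, the liver glycogen synthase, by 1.90 (SE 0.17). All 29 nuclear genes of oxidative phosphorylation fell, also when adjusted over the list alone (median -0.78; camera adjusted p = 9.32e-15; adjusted p = 0.279 with an estimated correlation). Sdhb, a subunit of succinate dehydrogenase, fell by 1.30 (SE 0.09).

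Drug metabolism had the lowest median among the lists with at least 8 measured members. Of 27 measured genes, 1 rose, 25 fell and 1 was not called (1 and 26 adjusted over the list alone), with a median of -2.44 (camera adjusted p = 1.02e-08; adjusted p = 0.279 with an estimated correlation). Gsta2, a glutathione transferase, fell from 15.1 ± 2.2 to 0.188 ± 0.120 CPM, and Nr1i3, the xenobiotic receptor CAR, fell by 2.61 (SE 0.25). Cyp3a13 rose by 1.85 (SE 0.08). Of 27 growth hormone-dependent and male-biased genes, 2 rose, 16 fell and 9 were not called, the same adjusted over the list alone (camera adjusted p = 0.000585; adjusted p = 0.280 with an estimated correlation). Cyp2d9 fell by 1.77 (SE 0.15) and Ugt2b1 fell by 3.46 (SE 0.33); both belong to large families whose members share sequence. Of 14 measured NRF2 targets, 2 rose, 7 fell and 5 were not called, the same adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.337 with an estimated correlation). Ephx1, an epoxide hydrolase, fell by 2.98 (SE 0.20), while Hmox1, the haem oxygenase, rose by 1.86 (SE 0.12).

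Genes of the unfolded protein and integrated stress responses rose in C26. Of 26, 23 rose, 1 fell and 2 were not called, the same adjusted over the list alone (camera adjusted p = 1.49e-09; adjusted p = 0.271 with an estimated correlation). Xbp1, a transcription factor of the response, rose by 1.10 (SE 0.08), the chaperone Calr by 1.26 (SE 0.09) and the disulfide isomerase Pdia4 by 1.61 (SE 0.12). Of 30 ribosomal protein genes, 21 rose and 9 were not called (24 higher adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000239; adjusted p = 0.550 with an estimated correlation). Rplp0 rose by 0.54 (SE 0.07). Of 28 proteasome genes, 1 rose, 4 fell and 23 were not called, the same adjusted over the list alone (camera adjusted p = 0.864). The list median was 0.01 and its mean -0.02. Psmc4 rose by 0.31 (SE 0.07) and Psmb7 fell by 0.36 (SE 0.08).

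Markers of several non-hepatocyte cell types were higher in C26. Of 12 Kupffer cell markers, 11 rose and 1 was not called, also when adjusted over the list alone (median 0.95; camera adjusted p = 2.70e-06; adjusted p = 0.271 with an estimated correlation), among them Cd5l (1.40, SE 0.10) and Cd163 (1.58, SE 0.15). Of 11 measured markers of monocytes and neutrophils, 10 rose and 1 was not called, also when adjusted over the list alone (median 2.79; camera adjusted p = 0.00162; adjusted p = 0.280 with an estimated correlation). Csf3r went from 1.74 ± 0.64 to 7.42 ± 2.43 CPM and Ccr2 from 1.28 ± 0.58 to 7.79 ± 3.44 CPM. Of 13 sinusoidal endothelial markers, 11 rose and 2 were not called, also when adjusted over the list alone (median 0.71; camera adjusted p = 0.000612; adjusted p = 0.337 with an estimated correlation), among them Fcgr2b (1.03, SE 0.09). Of 12 stellate cell markers, 7 rose, 2 fell and 3 were not called (8 and 2 adjusted over the list alone; median 0.52; camera adjusted p = 0.0405; adjusted p = 0.549 with an estimated correlation and 0.0657 with the length and GC trend removed), with Dcn, which encodes decorin, at 1.25 (SE 0.10). Of 24 extracellular matrix genes, 18 rose and 6 were not called (20 higher adjusted over the list alone; median 1.45; camera adjusted p = 5.05e-07; adjusted p = 0.271 with an estimated correlation). Fn1, which encodes fibronectin and is also made by hepatocytes, rose from 1821 ± 176 to 6278 ± 552 CPM, and Mmp14 rose by 2.28 (SE 0.12).

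**Figure D3:**
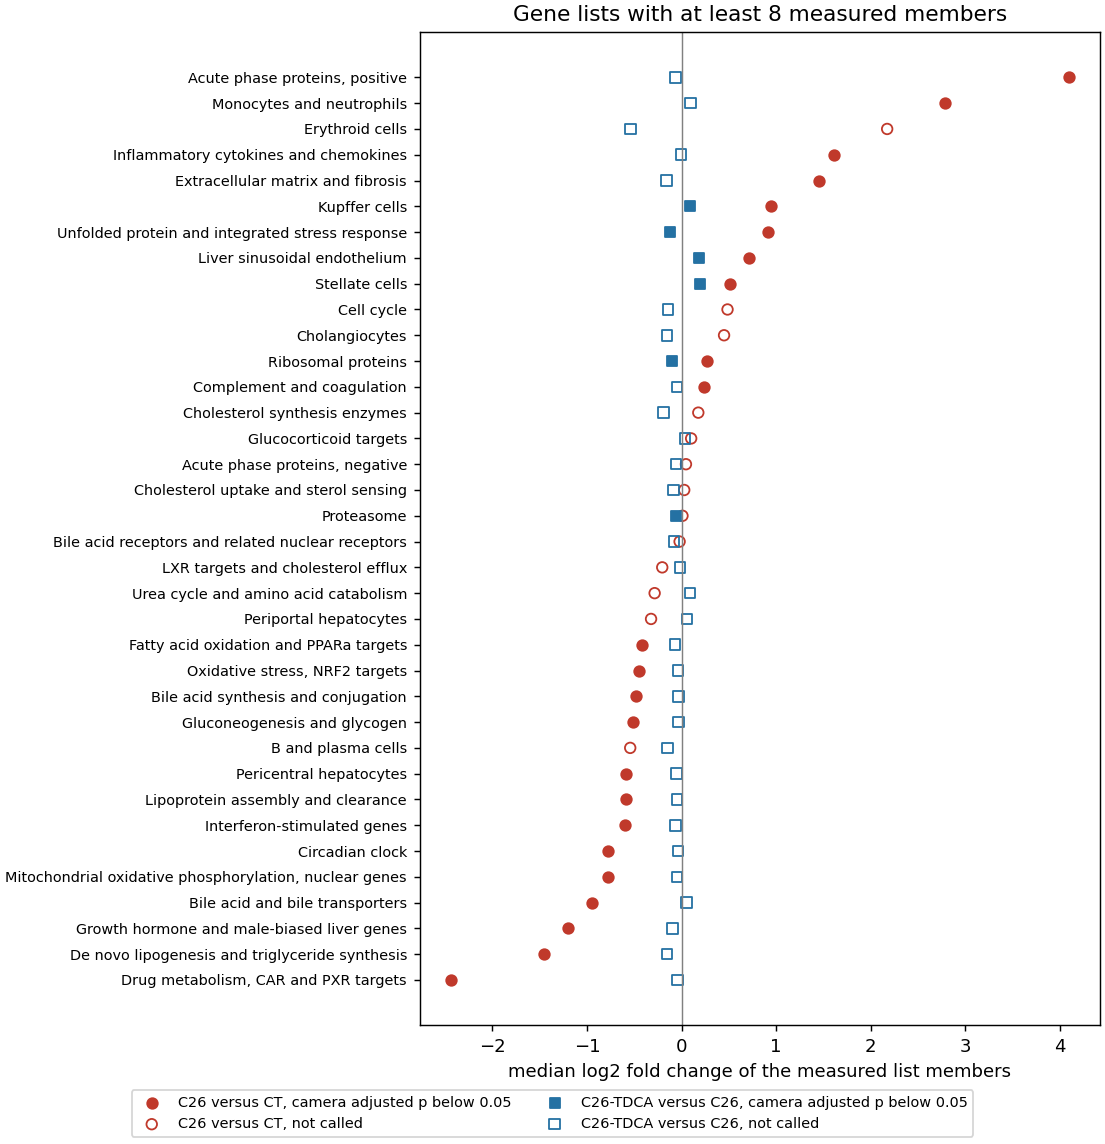
Median log2 fold change of the measured members of each gene list with at least 8 measured members, for C26 against CT (circles) and C26-TDCA against C26 (squares); filled symbols had a camera adjusted p under 0.05 with the preset correlation. The positive acute phase list lay at 4.09 and the drug metabolism list at -2.44 in C26 against CT, and the same lists lay at -0.06 and -0.04 in C26-TDCA against C26.

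The second comparison asked what daily TDCA changed in the liver of tumour-bearing mice, with cholesterol metabolism named as the subject by the series title. Of the 20 cholesterol synthesis enzymes, 18 uptake and sensing genes, 17 bile acid synthesis genes and 15 bile transporters, 0 were called between C26-TDCA and C26 by edgeR, over all genes or adjusted over the list alone. Of these 70 genes, 5 had an unadjusted p under 0.05 and DESeq2 called 0. Outside these 4 lists, 1 of 23 lipoprotein genes was called as higher and 0 of 15 LXR target and efflux genes were called. Among the genes higher in C26-TDCA, Kmt2c, a histone methyltransferase, went from 23.9 ± 4.9 CPM (n = 8) to 40.4 ± 9.0 CPM (n = 8; 0.76, SE 0.13, adjusted p = 0.0117), and F8, which encodes clotting factor VIII, made by sinusoidal endothelium, from 21.3 ± 4.0 to 33.3 ± 3.6 CPM (0.64, SE 0.10, adjusted p = 0.00518; 0.31 and not called with the length and GC trend removed). Zfp871, a zinc finger gene on chromosome 17 from 32765496 to 32788287 on the minus strand in GRCm38, went from 2.39 ± 2.61 (1.48 without C26 01) to 16.4 ± 8.5 CPM (2.74, SE 0.45, adjusted p = 0.0111). In CT, Zfp871 lay at 5.10 to 14.2 CPM, above every C26 library except C26 01.

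In all, 256 genes were higher and 35 lower in C26-TDCA by edgeR, with a median absolute log2 fold change of 0.44, and 25 higher and 0 lower genes exceeded 1 log2 unit. At an unadjusted p under 0.05 there were 2335 genes. Hgf, the hepatocyte growth factor of stellate cells, was higher by 0.73 (SE 0.17), Prex2, an exchange factor, by 0.77 (SE 0.16), Exph5 by 0.94 (SE 0.22) and Bdp1, a subunit of a polymerase III initiation factor, by 0.78 (SE 0.15). Myh14, a non-muscle myosin, fell from 16.7 ± 1.9 to 12.3 ± 1.0 CPM (-0.44, SE 0.07, adjusted p = 0.0117), and all 8 C26-TDCA libraries lay below all 8 C26 libraries. Cad, which starts pyrimidine synthesis, fell by 0.36 (SE 0.09). The count depended on the fit: with C26-TDCA and C26 alone in the model, 41 genes were higher and 4 lower, and glmTreat at 0.5 log2 units called 0 in each direction, where DESeq2 called 434 and 104 without such a bound. Left out singly, C26-TDCA 04 left 54 higher and 5 lower genes, while C26 01 gave 527 and 67 and C26-TDCA 08 gave 436 and 62.

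The genes called higher in C26-TDCA had a median transcript length of 7462 nt and a GC content of 42.6%, against 3151 nt and 49.3% over all tested genes. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.255 with transcript length and -0.422 with GC. The slope of log2 CPM on GC, per 10 points, was 0.106 ± 0.0796 (n = 8) in C26, -0.0269 ± 0.0619 (n = 8) in C26-TDCA and -0.105 ± 0.0552 (n = 6) in CT (C26-TDCA against C26, two-sided exact permutation p = 0.00171, adjusted p = 0.00513 over 21 tests). Between C26 and CT the GC slope differed by 0.211 (exact permutation p = 0.000333, adjusted p = 0.00117). The slope on transcript length, per doubling, was not called between C26-TDCA and C26 (difference 0.0271, exact permutation p = 0.202, adjusted p = 0.265). With the length and GC trend of each library removed, an alternative chosen after the data were seen, 14 genes were higher and 9 lower. Zfp871, Kmt2c and Myh14 were among those called, at 2.42, 0.44 and -0.37 against 2.74, 0.76 and -0.44 before. The calls of F8 (0.31), Prex2 (0.42), Bdp1 (0.49), Hgf (0.64), Exph5 (0.85), Cad (-0.35) and Bmp2 (0.45) ended, and Apob, the structural protein of hepatic lipoproteins, went from 0.38 (SE 0.09) to 0.02 and was no longer called. Hgf, Exph5, Cad, Bmp2 and Apob were also not called with C26-TDCA and C26 alone in the model. Zfp871 stood at 8.79 CPM in C26 01 and at 1.05 to 2.03 CPM in the other 7 C26 libraries, and at 1.68 CPM in C26-TDCA 08 and at 8.15 to 26.8 CPM in the other 7 C26-TDCA libraries.

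**Figure D4:**
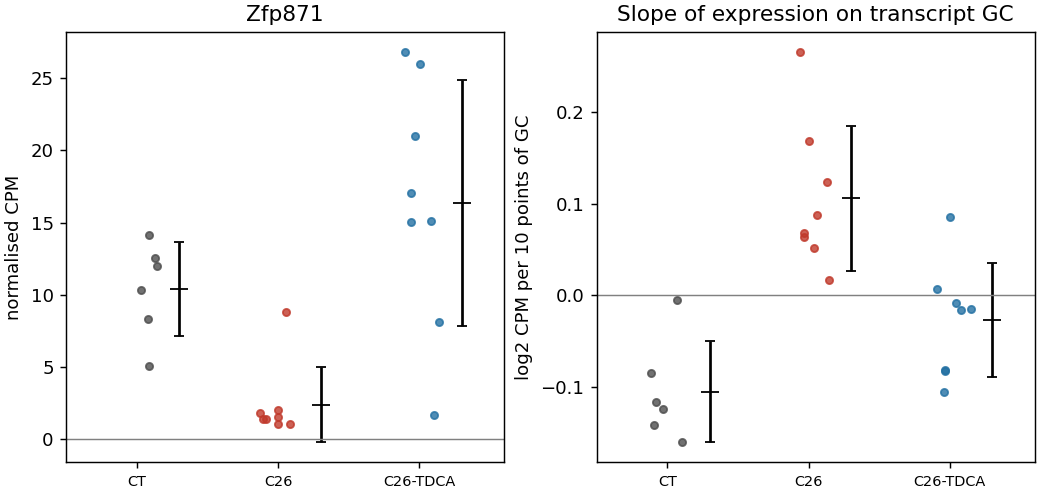
Left, normalised CPM of Zfp871 per library, and right, the slope of log2 CPM on transcript GC content per 10 points of GC, with the mean and SD in black for CT (n = 6), C26 (n = 8) and C26-TDCA (n = 8). C26 01 stood at 8.79 CPM and C26-TDCA 08 at 1.68 CPM of Zfp871, and the mean GC slope was 0.106 in C26 and -0.0269 in C26-TDCA.

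The genes of bile acid and cholesterol metabolism are given with the interval of the difference, since a missed threshold does not show equal levels. Cyp7a1 was at 32.2 ± 27.9 CPM in C26-TDCA and 25.1 ± 18.6 CPM in C26 (0.37, approximate 95% interval -0.71 to 1.44, adjusted p = 0.801). Cyp8b1 differed by -0.13 (-0.63 to 0.38), Slc10a1 by -0.08 (-0.26 to 0.10) and Sqle by -0.27 (-0.85 to 0.30). Abca1 was at 487 ± 113 and 366 ± 128 CPM (0.41, SE 0.17, adjusted p = 0.213). The median log2 fold change was -0.19 over the cholesterol synthesis enzymes (camera adjusted p = 0.107), -0.09 over uptake and sensing genes (adjusted p = 0.30), -0.03 over bile acid synthesis (adjusted p = 0.834) and 0.05 over transporters (adjusted p = 0.554). Simulated 2-fold changes were recovered in 84.8% and 1.5-fold changes in 60.6% of 66 tested genes each for this comparison, with 6.43% of calls on unchanged genes. The simulated genes were drawn at random, so these shares do not hold for genes with wide intervals such as Cyp7a1. The simulated counts were independent between genes and held no length or GC trend. The 6.43% is therefore not an estimate of the false share among the real calls.

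Camera called 6 lists between C26-TDCA and C26. Sinusoidal endothelial markers were higher (median 0.19, adjusted p = 0.00129), with 1 of 13 called, Bmp2 (0.40, SE 0.11), and 3 adjusted over the list alone. Stellate cell markers were higher (median 0.20, adjusted p = 0.00129), with 1 of 12 called, Hgf, and 3 adjusted over the list alone. Kupffer cell markers were higher (median 0.09, adjusted p = 0.0454), with 0 of 12 called and 2 adjusted over the list alone; Cd163 stood at 0.42 (SE 0.13, adjusted p = 0.103). Ribosomal proteins (median -0.10, adjusted p = 5.12e-05), the unfolded protein and integrated stress responses (median -0.12, adjusted p = 0.0151) and the proteasome (median -0.06, adjusted p = 0.0434; 0.0616 with the length and GC trend removed) were lower as lists, with 0 members called in each by edgeR, also when adjusted over the list alone, and 0 by DESeq2. At an unadjusted p under 0.05 there were 4 ribosomal, 5 stress response and 2 proteasome genes, and 3 Kupffer cell markers, of which DESeq2 called 1. With the length and GC trend removed, the list of the urea cycle and amino acid catabolism was called as higher (adjusted p = 0.00983). For each of the 6 lists that camera called, the call was lost, at adjusted p = 0.886 with an estimated correlation, and fry, which asks whether a list moves in 1 direction on balance, gave adjusted p-values of 0.737 to 0.764. The positive acute phase list stood at -0.06 (adjusted p = 0.344), with 0 of 32 members called by edgeR or DESeq2 and 3 at an unadjusted p under 0.05.

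The third comparison set the TDCA-treated tumour-bearing mice against the sham-injected mice. As in the first comparison, acute phase transcripts were high and bile acid, lipid and drug metabolism transcripts low in C26-TDCA. Of 21 lipogenesis genes 20 fell and 1 rose, also when adjusted over the list alone, and of 27 drug metabolism genes 23 fell, 1 rose and 3 were not called (24 and 1 adjusted over the list alone; camera adjusted p = 2.62e-08 and adjusted p = 0.237 with an estimated correlation for each list). Saa2 stood at 25710 ± 2917 CPM (n = 8) against 20.2 ± 26.1 CPM (n = 6), Lcn2 at 2101 ± 298 against 2.79 ± 2.79 CPM, Car3 at 12.2 ± 10.4 against 4400 ± 243 CPM and Cyp3a11 at 21.6 ± 22.1 against 2737 ± 389 CPM; without CT 05 the CT means were 9.62 CPM for Saa2 and 1.67 CPM for Lcn2. The carboxylesterases Ces1f and Ces1d, members of a family with similar sequences, fell by 6.73 (SE 0.99) and 6.32 (SE 0.56), with a C26-TDCA mean of 4.59 CPM for Ces1f, or 2.69 CPM without C26-TDCA 01. EdgeR called 4250 genes higher and 4175 lower, of which 1642 and 1069 changed more than 1 log2 unit, and glmTreat at 0.5 called 1992 and 1560.

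Cyp7a1 fell by 3.53 (SE 0.61, adjusted p = 2.50e-05), Cyp27a1 by 1.27 (SE 0.18), Slc10a1 by 1.49 (SE 0.10) and Nr1h4 by 0.71 (SE 0.14) against CT, and Cyp8b1 went from 323 ± 32 to 72.0 ± 34.2 CPM. Of 17 bile acid synthesis genes, 2 rose, 12 fell and 3 were not called, also when adjusted over the list alone (camera adjusted p = 0.00120; adjusted p = 0.237 with an estimated correlation). Sqle rose by 1.74 (SE 0.34) and Abca1 by 1.32 (SE 0.18). Hmgcs1 stood at 0.77 (SE 0.42, adjusted p = 0.115), but was called with replicate numbers as a block (0.70) and with the same libraries unblocked (0.91). Of the 20 cholesterol synthesis enzymes, 2 rose, 4 fell and 14 were not called, also when adjusted over the list alone (camera adjusted p = 0.475). Their median of -0.01 became 0.04 with upper-quartile scaling. Of 32 positive acute phase genes, 31 rose and 1 was not called, also when adjusted over the list alone (camera adjusted p = 1.00e-31; adjusted p = 0.00321 with an estimated correlation). Of 30 ribosomal protein genes, 13 rose and 17 were not called (8 higher adjusted over the list alone; camera adjusted p = 0.0241; adjusted p = 0.724 with an estimated correlation). Of 12 stellate cell markers, 9 rose, 1 fell and 2 were not called, also when adjusted over the list alone (camera adjusted p = 0.00349; adjusted p = 0.333 with an estimated correlation), with Hgf at 2.54 (SE 0.20).

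Whether TDCA moved genes against the tumour effect was asked of the log2 fold changes of C26 against CT and of C26-TDCA against C26, which share the C26 libraries. Of the 256 genes higher with TDCA, 149 were lower in C26 than in CT, where independent lists would share 74.8, and 25 were higher in C26, where independent lists would share 73.9. Of the 35 genes lower with TDCA, 19 were higher in C26 (10.1 for independent lists) and 4 lower (10.2). Over the 14785 genes the correlation was -0.12 and the covariance -0.0294. In 50 simulations with unchanged groups, the mean correlation was -0.467 and the mean covariance -0.0179, from which the observed covariance differed by -0.0116. These simulations held no tumour effect and drew each gene independently, so they do not give the range that chance allows in these data. With the C26 libraries divided between the comparisons in 70 ways, the mean correlation was -0.04 (-0.36 to 0.30) and the mean covariance -0.0073 (-0.0957 to 0.108). In 40 refits of such divisions, a median of 2.5 genes were lower in C26 and higher with TDCA, from 0 to 253, where independent lists would share 0.733; the counts in the same direction reached 210 (higher with both) and 157 (lower with both), each with a median of 0. These refits called a median of 3 genes higher with TDCA, too few to say how much of the overlap of 149 came from the shared C26 libraries. Across genes, GC content had a Spearman correlation of 0.149 with the change in C26 against CT. With the change in C26-TDCA against C26 it was -0.422. The GC trend between libraries may thus have added to the opposite directions, and the overlap was not counted with the trend removed.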

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

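The tests of regrouped libraries, of the length and GC trend, of exchanged labels and of cell shares in this part were chosen after the results were seen. Over 3 groups each for the 101 genes named in the text and 5 library properties, 24 of 318 sets (7.55%), all of genes, held a library far from the others of its group, where chance gives about 1 in 20 groups, and genes of one library are not independent. In CT 05, A2m (10.8 CPM, next 0.333), Lcn2 (8.40), Saa2 (73.2) and Reg3b (0.226) were high. In C26 02, Ces1d (59.2 CPM, next 10.3), Me1 (91.2), Pklr (114) and Ugp2 (110.0) were high. In the other CT libraries, Cad was low (9.47) in CT 01, Prex2 low (2.62) in CT 02, Ces1f high (540.0) in CT 06, Fcgr2b high (58.8) and Npc1 low (176) in CT 07, and Abcc2 (728) and Cyp1a2 (886) high and Ccr2 low (0.21) in CT 08. In the other tumour libraries, Ccr2 was high (15.9) in C26 04, Akr1d1 low (33.1) in C26-TDCA 02, Fetub high (1010) and Fn1 (3680) and Lrp1 (1480) low in C26-TDCA 07, and Bdp1 low (9.82) in C26-TDCA 08. Zfp871 was high in C26 01 (8.79, next 2.03) and low in C26-TDCA 08 (1.68, next 8.15). No explanation was tested for the libraries CT 05 and C26 02.

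The 291 genes called between C26-TDCA and C26 were weighed first. Only 1 of 100 splits of the 16 libraries, the real one, gave as many, with 226 in the highest other split. A chance division is thus unlikely to give this count, though 100 drawn splits cannot exclude it. Removal of the length and GC trend ended the calls of 242 higher genes, whose median change fell from 0.458 to 0.216 log2 units, by more than the median SE of 0.104, so the trend may account for part of these. The 33 lower calls that ended went from 0.290 to 0.225 in size, by just less than the median SE of 0.0684, which decides nothing for them. After the removal 16 calls remained (14 higher, 2 lower), so the trend as fitted did not account for every call. Some of these had smaller changes, such as Kmt2c (0.756 to 0.443), and some did not, such as Vipr1 (0.471 to 0.534). A fit that removed the trend only in part could leave such calls, so they do not exclude it. With fewer genes past the threshold, the adjustment was stricter. A lower share of hepatocytes would raise the markers of other cell types alike, and the shifts of 8 such lists ran from -0.408 for erythroid cells (larger SD 0.701) through -0.196 for T and NK cells, -0.125 for cholangiocytes and -0.0681 for B and plasma cells to 0.247 for stellate cells, but this difference of 0.655 was less than 2 times the larger SD, so it decides nothing. An effect of TDCA, the length and GC trend, and a shift in cell shares stay open. What made the trend differ between the groups was not tested.

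Scored with 100 genes chosen without it, 2 of the 16 tumour libraries, C26 01 (0.736) and C26-TDCA 08 (-0.878), lay nearer the other tumour group, and 3 did with the trend removed, with C26-TDCA 01 at -0.00838. Exchanged labels of C26 01 and C26-TDCA 08 may explain their place, and mice that differed in their response stay open too, as untested. An exchange would dilute the difference between the groups and not make the 291 calls; without both libraries 691 genes were higher and 94 lower, though libraries left out for lying near the other group favour more calls.

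Markers of non-parenchymal cells rose in C26 against CT by 2.26 (SD 0.516 between C26 libraries) for monocytes and neutrophils, 0.999 (SD 0.171) for Kupffer cells, 0.68 (SD 0.266) for sinusoidal endothelium and 0.549 (SD 0.227) for stellate cells. The highest and lowest shift differed by 1.71, more than 2 times the larger SD, which argues against a lower share of hepatocytes as the only source. More monocytes and neutrophils, or higher expression in these cells, may have contributed, and this stays open. Between C26-TDCA and C26, the mean score of the sinusoidal endothelial, stellate and Kupffer cell markers was 0.937 ± 0.113 against 0.743 ± 0.202 (two-sided exact permutation p = 0.0272). A difference between the groups and one between single libraries cannot be told apart here, because the 3 lists were chosen after the list test had called them.

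The counts against CT were set against other splits too. In C26 against CT, 1 of 100 splits of the 14 libraries, the real one, gave 8587 genes, with 5455 in the highest other. In C26-TDCA against CT, 1 of 100 gave 8425, with 5713 in the highest other. A chance division of the libraries is thus unlikely to give either count.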

How the results depend on the processing

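The fits with the length and GC trend removed, without C26 01 and C26-TDCA 08, and with the block's libraries unblocked were chosen after the results were seen; the other alternatives were not. The counts of called genes against CT stayed within 1.5 times under every alternative except glmTreat at 0.5 log2 units (C26: 1980 higher, 1633 lower; C26-TDCA: 1992 and 1560), which by construction asks for larger changes. Between C26-TDCA and C26, DESeq2 size factors (257 higher, 41 lower), upper-quartile scaling (204 and 48) and no filter (244 and 32) stayed within 1.5 times of 256 and 35. The counts were 41 and 4 with only the 2 groups, 434 and 104 with DESeq2, 409 and 59 with voomWithQualityWeights, 14 and 9 with the trend removed, 691 and 94 without C26 01 and C26-TDCA 08, and 173 and 96 with both changes; glmTreat gave 0 and 0, beside 2335 genes at an unadjusted edgeR p under 0.05. Whether the replicate numbers pair some of the mice stays undecided. Between C26-TDCA and C26, correlations were -0.204 to 0.337, over 0.1 in 5 of 8 pairs where all were required, and 2 pairs were each other's best match. A block of replicate numbers gave 19 and 2, against 41 and 4 for the same libraries unblocked. The block also ended the list calls of interferon-stimulated genes, NRF2 targets, pericentral hepatocytes and stellate cells in C26 against CT. Between C26-TDCA and C26 it ended those of the proteasome and Kupffer cells, and in C26-TDCA against CT it added erythroid cells. Hmgcs1 in C26-TDCA against CT (0.77, not called) was called with the block (0.70) and with the same libraries unblocked (0.91), and Srebf2 with the block (0.23). The cause was not tested for any of these changes. Leaving out 1 library gave 54 to 527 higher and 5 to 67 lower genes: higher without C26 01 (527), 05 (86), 06 (92), 07 (170) or 08 (114), and without C26-TDCA 02 (146), 03 (92), 04 (54), 05 (142), 06 (119) or 08 (436); lower without C26 01 (67), 05 (14), 06 (11) or 08 (13), and without C26-TDCA 03 (13), 04 (5), 05 (17), 06 (19) or 08 (62). Against CT the ranges were 4078 to 4341 higher and 4115 to 4367 lower for C26, and 4071 to 4282 and 3980 to 4201 for C26-TDCA. Camera called 23 lists in C26 and 23 in C26-TDCA against CT and 6 between them. With an estimated correlation it called 1, 1 and 0. Fry, which does not compare a list with other genes, called 33, 31 and 0. The list test with the trend removed used log2 CPM in place of voom values, so its changes cannot be put down to the trend alone. It ended the calls of stellate cells in C26 against CT (camera adjusted p = 0.0657) and the proteasome between C26-TDCA and C26 (0.0616). In C26-TDCA against CT it ended that of pericentral hepatocytes (0.0502). It added erythroid cells in C26 against CT and the urea cycle between C26-TDCA and C26. The correlation of the TDCA and tumour effects went to -0.0381 and their covariance to -0.00731 with the C26 libraries divided, and the covariance to -0.0118 over genes with at least 10 CPM; the cause was not tested. No named gene or list called with either setting changed direction under these alternatives, for genes without the single libraries left out; among uncalled results the direction changed in 13 list tests, such as the proteasome in C26 against CT with the trend removed, and for 11 values of named genes. Of 96 named genes between C26-TDCA and C26, 16 were no longer called with glmTreat, 13 with the trend removed, 9 with only the 2 groups, 10 with the block and 1 with upper-quartile scaling, while DESeq2 called 5 more of 87 and voomWithQualityWeights 2 more. Of 172 in C26 against CT, 23 were no longer called with glmTreat and 3 with the trend removed (Srebf2 among them), and of 174 in C26-TDCA against CT, 20 and 2. Depth set a floor of 0.11 to 0.18 CPM (3 counts), below which genes such as Acpp and Trat1 in CT have no measured level.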

Other observations

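Further gene groups differed between C26 and CT livers; only the choice to describe the library C26 02 was made after its values were seen. Of 19 measured clock genes, 2 rose, 14 fell and 3 were not called (2 and 15 adjusted over the list alone; camera adjusted p = 0.00492; adjusted p = 0.279 with an estimated correlation). Usp2, a clock-controlled deubiquitinase, fell by 2.84 (SE 0.24) and Tef, a clock output factor, by 1.36 (SE 0.20), while Nfil3, a repressor of the same target sites, rose by 1.97 (SE 0.18). The hours of sampling were not used here. Of 17 glucocorticoid targets, 6 rose, 6 fell and 5 were not called (7 and 6 adjusted over the list alone; camera adjusted p = 0.371), with the metallothionein Mt2 up by 5.23 (SE 0.20) and Hsd11b1, which regenerates corticosterone, down by 1.33 (SE 0.12). Of 31 genes of the urea cycle and amino acid catabolism, 10 rose, 16 fell and 5 were not called (11 and 17 adjusted over the list alone; camera adjusted p = 0.515). Otc, the ornithine carbamoyltransferase, fell by 1.30 (SE 0.09) and Slc25a15, the mitochondrial ornithine carrier, rose by 1.19 (SE 0.11). Of 27 measured cell cycle genes, 9 rose, 5 fell and 13 were not called, the same adjusted over the list alone (camera adjusted p = 0.383); Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 0.70 ± 0.31 to 14.7 ± 13.2 CPM and Tk1 fell from 41.6 ± 5.7 to 9.06 ± 3.13 CPM.

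Both zones of the hepatocyte plate held genes that rose and genes that fell. Of 15 pericentral genes, 1 rose, 9 fell and 5 were not called (1 and 10 adjusted over the list alone; camera adjusted p = 0.0373; adjusted p = 0.582 with an estimated correlation), and of 15 periportal genes, 5 rose, 8 fell and 2 were not called, the same adjusted over the list alone (camera adjusted p = 0.653). The pericentral Cyp1a2 fell by 2.44 (SE 0.34), and the periportal Etnppl fell from 233 ± 24 to 6.94 ± 4.15 CPM. Of 9 measured cholangiocyte markers, 3 rose and 6 were not called, the same adjusted over the list alone (camera adjusted p = 0.0962). Spp1, also made by macrophages, rose from 18.8 ± 3.6 to 411 ± 172 CPM, and Sox9 rose by 4.11 (SE 0.42). Of 8 measured erythroid markers, 6 rose, 1 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 0.0863), with Hbb-bs at 37.5 ± 12.4 and 169 ± 95 CPM. Of 12 measured B and plasma cell markers, 2 rose, 4 fell and 6 were not called (1 and 4 adjusted over the list alone; camera adjusted p = 0.399), and the antigen presentation genes Cd74 and H2-Aa fell by 1.35 (SE 0.20) and 1.27 (SE 0.21). Of 4 measured T and NK cell markers, 2 fell and 2 were not called, the same adjusted over the list alone (camera adjusted p = 0.307). The lists of exocrine pancreas, adipocytes and intestinal epithelium had 1, 3 and 3 measured members and camera adjusted p-values of 0.205, 0.345 and 0.0792; 1 of 1, 2 of 3 and 2 of 3 members fell, and 0, 1 and 0 rose, the same adjusted over the list alone.

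One tumour library lay nearer to the controls than the others. C26 02 had the lowest component 1 value of the tumour libraries, 4.01, and the highest C26 levels of Car3 (308 CPM, against 4400 ± 243 CPM in CT) and Cyp3a11 (312 CPM). Without it, 4341 genes were higher and 4367 lower in C26 than in CT, and 229 higher and 51 lower in C26-TDCA than in C26. Within the tumour mice, a mean of 42.8 more genes was detected with at least 1 count in C26-TDCA than in C26 (n = 8 each, two-sided exact permutation p = 0.0202, adjusted p = 0.0424 over 21 tests), and a mean of 186 more with at least 10 counts (exact permutation p = 0.230, adjusted p = 0.284).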
